A study of Mus musculus with 768 samples.

How the data were processed

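Single spleen B cells of IgE reporter mice were sorted into 96-well plates, and full-length cDNA was made with 25 cycles of PCR and sequenced as paired reads of 150 nt, per the labels' protocols. The values are raw counts of reads per gene symbol and well, as deposited by the authors. Reads had been aligned with HISAT2 2.1.0 to mm10, per the submitters' processing notes, which also name StringTie 2.0 without its role. The counting tool, the gene annotation and the strand setting are not given in the sources used here. Overlapping and antisense genes are therefore uncertain, as are near-identical copies such as Ly6c2, the Bcl2a1 genes, the H2 genes and the Gbp and Igtp families. The library protocol has no molecular identifiers, so counts are PCR reads, not molecules.

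The table held 23284 gene symbols and 5 further entries that name no gene and took 75.2% of all counts. Of all counts, 55.6% were assigned to no annotated feature, 10.1% were not uniquely aligned, 6.59% were not aligned, 2.64% had low alignment quality and 0.283% were ambiguous. The first of these shares depends on the annotation and strand setting. These entries were left out of library sizes. Rn45s took 19.6% of the counts in genes and was kept in the totals, with an alternative without it. None of the 12 immunoglobulin constant genes and none of the 13 mitochondrially encoded genes sought matched a symbol, so the planned results on isotypes and the planned mitochondrial limit of 25% were not used here. Symbols of the fixed lists were matched directly or through older synonyms, such as Igj for Jchain and 2010001M09Rik for Mzb1. Of the STAT6-responsive list 22 of 24 genes were in the table, and of the germinal center program 25 of 26.

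Column names gave 8 plates of 96 wells, of which 12 wells carried the mark PC and were set apart. None of the names matched a sample label, so the comparison of 384 cells per arm was not run, the plates were read as technical batches and no plates were joined into groups. A well was kept with at least 500 genes and 10000 gene counts. The deepest kept well had 1633010 gene counts and the shallowest 11904, so a value from 1 well has a precision that differs widely between wells. Levels are counts summed over cells and scaled to CPM with exact Poisson intervals. Shares of cells at 10 CPM or more have exact binomial (Clopper-Pearson) intervals. All have 95% confidence and cover counting error only. A count of 0 allows up to 3 counts, a limit on 1 side. Ratios are log2 of summed CPM plus a pseudocount of 1, which understates the change of low genes.

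Cells were clustered on log CPM of the 2000 most variable genes with 20 principal components, 15 neighbours and Leiden at resolution 0.5. A cluster was named where at least 50% of a marker set, and at least 3 markers, were found in a share of its cells 10 points above all other cells, by a margin of 20 points over the next set. This naming rule was set after the data were seen. No doublet caller was run, since each well was sorted to hold 1 cell. The lists, markers, cell filter, clustering settings and rule for named genes were chosen before the data were examined.

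Because the arms could not be compared, the planned comparison of expression and lists was applied to plasmablast-like over germinal center B-like cells, a contrast chosen after the data were seen. For it all list genes and markers were left out of the variable genes. Of 6 resolutions looked at, 0.5 gave a germinal center B-like cluster led in part by the naive and memory markers Sell and Ccr6. At 0.7, 0.8 and 1.0, 1 or 2 markers of another class also led a cluster of these classes. Resolution 1.2 was chosen after these outcomes were seen, because none did there; none did at 1.5 either. It gave 283 plasmablast-like, 255 germinal center B-like, 17 naive or follicular B-like and 196 unnamed cells. With the planned clustering it shared 281 plasmablast-like and 250 germinal center B-like cells.

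The rule for named genes took the 12 largest ratios in each direction among genes with at least 20 CPM in a class, at 10 CPM or more in 10% of its cells, and moved the same way in summed CPM, mean CPM and share of cells. Predicted genes, pseudogenes and immunoglobulin segments were left out, as were genes used for clustering and markers of the 2 classes. It added up to 4 genes per list and a set of genes always named. For lists, genes with a mean of at least 5 CPM were measured, 8799 genes in all, and a list's median was ranked among 10000 random lists of the same size matched on expression. Gene positions are those of GENCODE for GRCm38, which is mm10.

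Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9 was used. The ratio step was tested on simulated data with 200 wells per class and 6137 genes. Simulated 2-fold changes (log2 of 1) were recovered at a median log2 of 1.02 and 4-fold changes at 2.01, after the median of unchanged genes was subtracted. Only 100 genes were changed by each fold, and both simulated classes were drawn from kept wells at random. Ratios of the class comparison are not centred this way, so their offset and the classes' unequal gene reads were not tested. Alternatives covered cell filters, thinning to 1 depth, scaling, pseudocount, detection limits, filters on low genes, clustering settings and leaving out each plate. Scaling without Rn45s, the clusterings without list genes and every setting of the class comparison were added after seeing the data, as were counts relative to the median of all genes and values within plates.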

Results

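Single B cells were sorted from the spleens of 8-week-old IgE reporter mice on the C57BL/6 background, 7 days after immunization with NP-OVA, a hapten coupled to ovalbumin. The recipients had been given ovalbumin-specific OT-2 TH2 cells that could or could not make IL-13, so the design asks how IL-13 from helper T cells affects antigen-specific IgE-positive B cells. The gate took live cells that bound NP and carried CD19 and the IgE reporter. The labels list samples of 1 sorted cell each, 384 from recipients of IL-13-sufficient cells and 384 from recipients of IL-13-deficient cells, and name no animal. The wells of the count table carry plate and well names that match no label, so no well could be placed in an arm. The comparison of the 2 arms was therefore not analysed here, and the table was treated as 1 pooled sample without replicates. All values below describe that pool, the 8 plates in it, or classes of cells within it, and no significance test was run.

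Of 756 wells not marked PC, 751 were kept as cells, which is 99.3% with an exact binomial interval of 98.5 to 99.8%. Kept wells held a median of 504956 reads in genes, with quartiles of 340890 and 775096 and a range of 11904 to 1633010. A median of 3008 genes was detected per well. The ribosomal RNA precursor gene Rn45s took a median of 19.1% of a well's gene reads, with a range of 3.00 to 98.6%. Reads carried no molecular identifiers, so every interval and limit given here covers counting error only, at 95% confidence.

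The kept wells held B lineage cells. Cd79a, which encodes a signalling chain of the B cell receptor, was at 10 CPM (counts scaled to a fixed total per cell) or more in 95.1% of the 751 cells (exact binomial interval 93.3 to 96.5%), and Ms4a1, which encodes CD20, in 81.8% (78.8 to 84.5%). Cd19, part of the gate, reached that level in 66.3% (62.8 to 69.7%). At least 3 of 8 pan B markers were found in 734 cells. No cell held 3 markers of T cells, basophils or mast cells, dendritic cells or NK cells, where 0 of 751 cells allows a share of up to 0.399%. Only 1 cell held 3 neutrophil markers, 7 held 3 erythroid markers and 14 held 3 myeloid markers. Il4 and Il13 had 0 reads in all kept cells, which limits cells with a read to the same share and sets no limit on cells that express them at a low level. Immunoglobulin constant genes, Ighe among them, and mitochondrially encoded genes were not analysed here.

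Clustering split the cells mainly into germinal center B-like and plasmablast or plasma cell-like cells. The germinal center B-like class held 261 cells, 34.8% of the pool (31.3 to 38.3%). The plasmablast-like class held 283 cells, 37.7% (34.2 to 41.3%). The other 207 cells, 27.6% (24.4 to 30.9%), lay in 3 clusters that no marker set named. Over the 8 plates, the plasmablast-like share ranged from 7.37% to 69.2% with a median of 35.5%, and the germinal center B-like share from 15.4% to 54.7% with a median of 34.9%. The plasmablast-like share was at most 16.1% on plates 1 to 4 and at least 54.8% on plates 5 to 8. No plate therefore lay near its median. With clustering at resolution 1.0, or without cell cycle genes, 1 part of the germinal center B-like class lost its name and the class fell to 22.0%. Sdc1, which encodes the plasma cell marker CD138, and Bcl6, the germinal center repressor, were both at 10 CPM or more in 3 of 751 cells, and Prdm1, which encodes Blimp-1, and Bcl6 in 1 cell. Sdc1 and Aicda, the gene of the hypermutation enzyme, met in 28 of 751 cells (3.73%, 2.49 to 5.34%), of which 21 were among the 283 plasmablast-like cells of the clustering without list genes (7.42%, 4.65 to 11.1%).

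**Figure D1:**
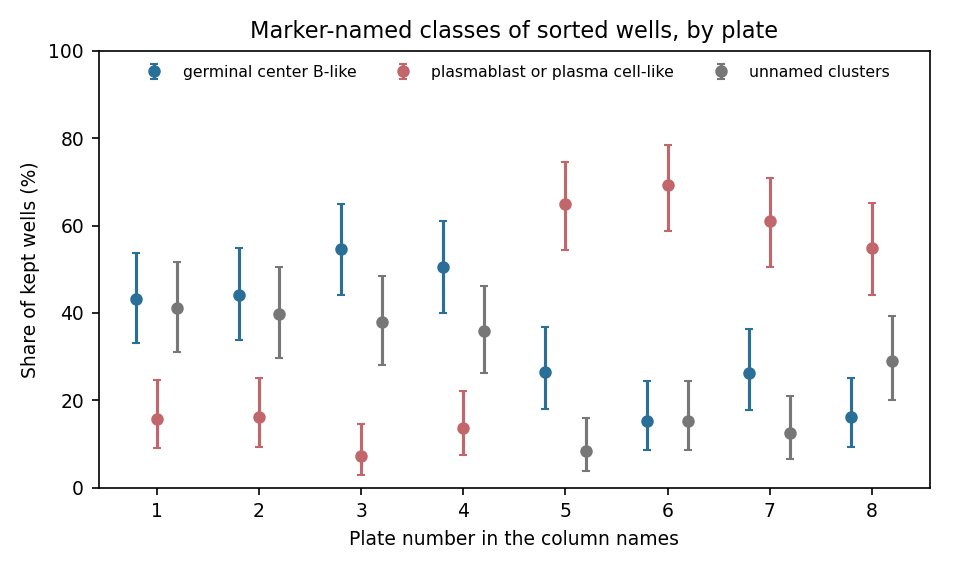
Share of kept wells, in percent, in each class (vertical axis) for each of the 8 plates (horizontal axis); points are shares and bars exact binomial 95% intervals. The plasmablast or plasma cell-like share spans 7.37% on plate 3 to 69.2% on plate 6, and the germinal center B-like share 15.4% on plate 6 to 54.7% on plate 3.

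Transcripts for the IL-4 and IL-13 receptors differed between these classes. For this comparison cells were clustered again without any gene of the fixed lists, which gave 283 plasmablast-like and 255 germinal center B-like cells. The plates contributed unequally, with 7 to 64 plasmablast-like and 14 to 50 germinal center B-like cells each, so that pooled values mix class with plate. Il4ra, which encodes the receptor chain shared by IL-4 and IL-13 (chromosome 7, 125552120 to 125579474 in mm10), was at 10 CPM or more in 71.0% of germinal center B-like cells (65.0 to 76.5%) and in 6.01% of plasmablast-like cells (3.54 to 9.44%). Its summed level was 408 CPM (exact Poisson interval 405 to 411) against 13.1 CPM (12.4 to 13.7), a log2 ratio of -4.86, and it was lower in plasmablast-like cells on 8 of 8 plates. Il2rg, which encodes the common gamma chain of the type I receptor (chromosome X, 101264378 to 101268255), was found in 88.6% (84.1 to 92.3%) and 43.1% (37.3 to 49.1%) respectively. Il4ra and Il2rg met in 63.5% of germinal center B-like cells (57.3 to 69.4%) and in 3.89% of plasmablast-like cells (1.96 to 6.85%).

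Il13ra1, the chain that pairs with Il4ra in the type II receptor and binds IL-13 (chromosome X, 36112110 to 36171259), was rare and ran the other way. It reached 10 CPM in 1 germinal center B-like cell, 0.392% (0.00993 to 2.17%), and in 7.42% of plasmablast-like cells (4.65 to 11.1%), at 24.5 CPM (23.6 to 25.5) against 0.118 CPM (0.0761 to 0.174). Its log2 ratio, plasmablast-like over germinal center B-like, was 4.51, and 3.76 without plate 5. It was higher in plasmablast-like cells on 6 plates and lower on 1. Il4ra and Il13ra1 were found together in 2 of the 751 kept cells, 0.266% (0.0323 to 0.959%). Il13ra2, which encodes the other IL-13-binding chain, had 0 reads in all kept cells.

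Downstream of these receptors, Stat6 (chromosome 10, 127642986 to 127660957) was found in 42.4% of germinal center B-like cells (36.2 to 48.7%) and 12.7% of plasmablast-like cells (9.07 to 17.2%). The Janus kinase gene Jak1 was found in 85.1% and 25.8%. Jak1 and Irs2 were named after their values were seen. Of 17 measured genes of the receptor and signalling list, 10 were at least 2-fold lower and 3 at least 2-fold higher in plasmablast-like cells. Relative to the median of all genes, 8 were 2-fold lower and 3 higher. The list's median log2 ratio was -1.44, below that of all but 0.48% of 10000 random lists matched on expression, and -1.32 without Bcl6, which had helped to name the classes. The phosphatase gene Ptpn6 was at 2199 CPM in germinal center B-like and 40.8 CPM in plasmablast-like cells. Cish, a cytokine-induced inhibitor of signalling, was found in 12.7% of plasmablast-like cells (9.07 to 17.2%) and in 0 of 255 germinal center B-like cells, which allows up to 1.18%. The insulin receptor substrate gene Irs2 was also higher in plasmablast-like cells, at 45.8 against 3.35 CPM. Within plates, the shares of Il4ra, Il2rg, Stat6 and Jak1 were lower in plasmablast-like cells on 8 of 8 plates, that of Irs2 was higher on 8 and that of Cish was higher on 5 and lower on 0. Median shares over plates, plasmablast-like and germinal center B-like, were 5.58% and 70.0% for Il4ra, 48.1% and 89.8% for Il2rg and 14.3% and 41.3% for Stat6.

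**Figure D2:**
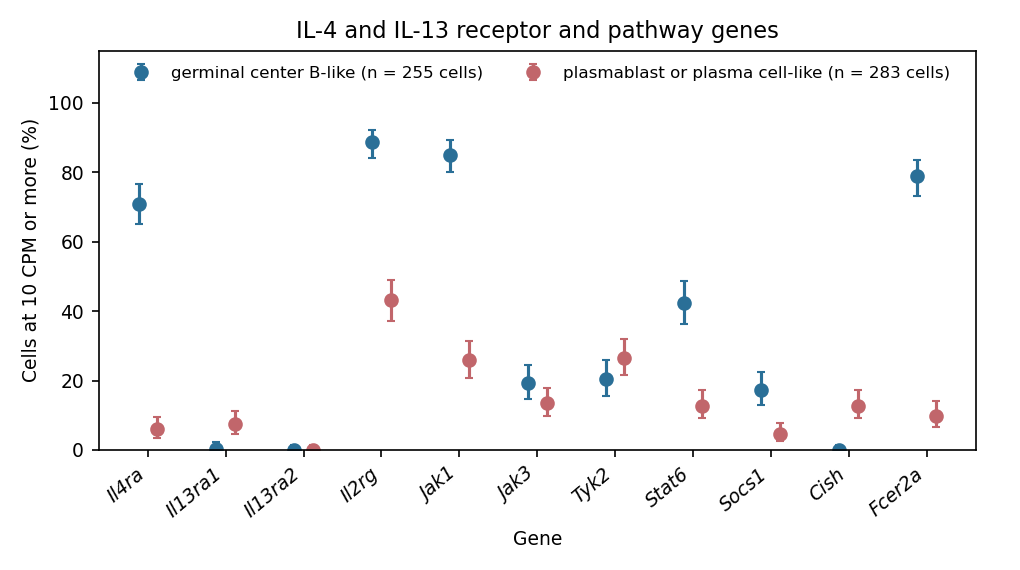
Share of cells, in percent, at 10 CPM or more (vertical axis) for genes of the IL-4 and IL-13 receptors and pathway (horizontal axis) in 255 germinal center B-like and 283 plasmablast or plasma cell-like cells; bars are exact binomial 95% intervals. Il4ra stands at 71.0% and 6.01%, Il13ra1 at 0.392% and 7.42%.

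Known STAT6-responsive genes of B cells were mostly lower in plasmablast-like cells. Of 18 measured, 12 were at least 2-fold lower and 5 at least 2-fold higher, with a median log2 ratio of -2.51 that lay below all 10000 random lists. Fcer2a, which encodes the low-affinity IgE receptor CD23, was at 993 CPM in germinal center B-like cells and 4.22 CPM in plasmablast-like cells, a log2 ratio of -7.57. The costimulatory gene Cd86 had a log2 ratio of -7.43. Ccnd2, a D-type cyclin gene on the same list, ran the other way at 7.25, and at 9.25 without plate 6. The list also holds Aicda and Xbp1, which helped to name the classes. Without them its median was -2.51. It could not move, because Aicda (-7.96) lies below it and Xbp1 (4.69) above it, so this does not test the overlap. H2-Aa, H2-Ab1, H2-Eb1, Cd74 and Cd86 are also members of the MHC class II list, so these lists are not independent.

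Secretory genes set the plasmablast-like cells apart. All but 4 of 34 measured genes of the unfolded protein response and secretory pathway were at least 2-fold higher, and none was 2-fold lower. Their median log2 ratio of 2.97 lay above all 10000 random lists, and it ranged from 2.65 to 3.19 over the 8 plates. None of the 34 genes had itself named the class. However, the naming markers include related secretory genes such as Xbp1, Derl3, Fkbp11, Edem1 and Creld2. The high rank is therefore not independent of the naming. The chaperone gene Hsp90b1 was at 17184 CPM in plasmablast-like and 222 CPM in germinal center B-like cells. Hspa5, which encodes the chaperone BiP and was named after its value was seen, was at 13370 against 1091 CPM. Ern1, which encodes the stress sensor IRE1, was found in 29.0% against 0.392% of cells, and in a higher share on 8 of 8 plates. Of the plasma cell program, 18 of 20 measured genes were at least 2-fold higher, but 14 of the 20 had named the class. The list's median log2 ratio was 4.71, and 2.73 without those 14. Prdm1, one of them, had a log2 ratio of 4.44, and 6.88 without plate 3.

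The 12 genes most raised in plasmablast-like cells, among genes used neither for clustering nor as markers of these 2 classes, were led by Bhlha15, which encodes the secretory cell factor MIST1, with a log2 ratio of 8.26. They included Creb3l2 (7.46) and the vesicle coat gene Sec24d (7.29), the surface genes Cd28 (6.92), Entpd1 (7.04), Tmem154 (7.51), Gpr160 (6.64) and Prlr (6.39), and Ckap4, Alpl, Pycr1 and Ccnd2. The 12 most lowered were led by Ciita (-8.18), the master regulator of MHC class II genes, and Spib (-8.12), a B cell transcription factor. The others were Myo1e, Fcer2a, Lrmp, Cd86, Emid1, Cr2, Cxcr5, Lta, Cd22 and Gsn. Cd22 stood at -7.41, and at -8.00 without plate 7. Gsn stood at -6.90, and at -7.59 without plate 1. Each of these 24 genes differed in 1 direction on all 8 plates.

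Antigen-presenting and helper-contact genes were lower in plasmablast-like cells. This held at 2-fold for 14 of 15 measured MHC class II genes (median log2 ratio -3.63), 12 of 17 genes of T and B cell contact (-3.67), 26 of 31 B cell receptor signalling genes (-2.29) and all 8 pan B markers (-4.37). It held for 15 of 21 light zone genes (-2.89), 11 of 14 dark zone genes (-1.68, and -1.32 without 3 naming markers) and 13 of 18 NF-kB targets (-2.74). Of the germinal center program, 22 of 25 measured genes were at least 2-fold lower, 13 of the 25 being markers that named the class. The list's median was -4.20, and -3.57 without those 13. Genes of class switching and hypermutation were lower for 18 of 25 (median -1.73). Relative to the median of all genes, the 2-fold counts were 13 for MHC class II, 11 for T and B cell contact, 21 for B cell receptor signalling, 8 for pan B, 15 for light zone, 8 for dark zone, 13 for NF-kB, 21 for germinal center program and 14 for switching genes. Within plates, the median over plates was -2.72 for dark zone and -2.48 for switching genes, and -1.91 and -1.83 relative to the median of all genes on each plate.

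Cells of both classes expressed the proliferation gene Mki67, named after its values were seen, at 10 CPM or more in 61.2% of germinal center B-like cells (54.9 to 67.2%) and 58.7% of plasmablast-like cells (52.7 to 64.5%), with summed levels of 478 and 256 CPM. Its share was higher in plasmablast-like cells on 3 plates and lower on 5. Other cycle genes differed more. Of 42 S phase genes, 40 were at least 2-fold lower in plasmablast-like cells (median log2 ratio -2.19), and of 50 measured G2 and M phase genes, 39 were (median -1.54). Relative to the median of all genes, 35 S phase genes and 25 G2 and M phase genes were 2-fold lower, with medians of -1.57 and -0.92. The median over plates was larger in size, at -2.52 for S phase and -2.90 for G2 and M phase genes. Relative to the median of all genes on each plate, these were -2.05 and -2.03. Single plates ranged from -5.66 to -1.72 for S phase and from -4.81 to -0.86 for G2 and M phase genes. Plates count equally here, although they held from 7 to 64 plasmablast-like cells.

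**Figure D3:**
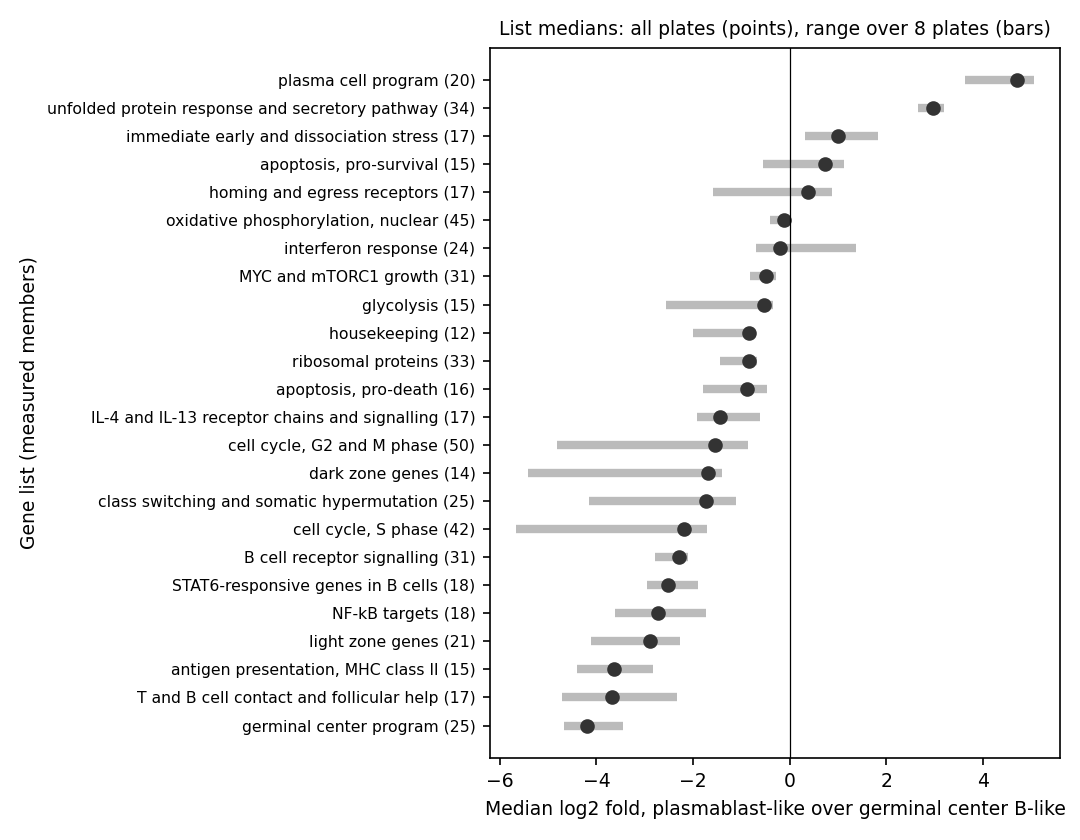
Median log2 ratio of summed CPM plus 1, plasmablast-like over germinal center B-like (horizontal axis), for 24 gene lists with the number of measured members (vertical axis); points are all plates together and grey bars the range over the 8 plates. Among these 24 lists, which leave out the marker sets, the plasma cell program lies highest at 4.71 and the germinal center program lowest at -4.20.

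Ratios between the classes are relative to all reads in genes, a total with no entry for the immunoglobulin constant genes sought. The median log2 ratio over 8799 measured genes was -0.62, and -0.04 with median-ratio scaling, so list medians near -0.62 do not stand apart. Relative to it, the receptor and signalling list lay at -0.82, the STAT6-responsive list at -1.89 and the secretory list at 3.59. Plasmablast-like wells also held fewer reads in genes, a median of 372402 against 837677, and more Rn45s, 23.6% against 13.0%. Plate medians of all counts per kept well ranged from 1961030 on plate 6 to 2534950 on plate 1. The median share in entries that name no gene was 66.8 to 68.7% on plates 1 to 4 and 81.6 to 82.8% on plates 5 to 8. Fewer reads in genes therefore need not mean less sequencing of a well. With wells thinned to 247857 reads each, Il4ra was still at 10 CPM or more in 71.1% and 5.51% of the cells. At least 1 Il4ra read was found in 77.5% (71.8 to 82.5%) and 21.7% (16.7 to 27.2%) of thinned cells, and in 85.1% and 29.3% without thinning. Thinning kept 253 of 255 germinal center B-like and 254 of 283 plasmablast-like cells.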

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

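The tests on the wells marked PC were chosen after the pattern was seen. These 12 wells lie outside the comparisons, and the meaning of the mark is not given in the sources used here. In 11 of them at least 5 of the 10 neutrophil markers were at 10 CPM or more. The granule protein genes Ngp and Mpo stood at medians of 17355 and 11419 CPM, and Epx, an eosinophil granule gene, at 1667 CPM. Lyz2, a lysozyme gene of myeloid cells, had a median of 9958 CPM, whereas 4 of 751 kept wells held it at 10 CPM or more. The exception was well H11 of plate 2, with 3 neutrophil markers and 82.6% of its gene counts in Rn45s.

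Reads carried over from kept wells would need a kept well with these genes, and 0 kept wells held 5 or more neutrophil markers, which argues against that source. RNA from several cell types may have been added to these wells, and 11 of 12 held at least 5 neutrophil and at least 3 pan B markers together. This count cannot decide, because all 12 wells held at least 5 pan B markers, so it only repeats the neutrophil count. In addition, 734 of 751 kept wells held at least 3 pan B markers, so carry-over of pan B reads was not excluded. What was put into them stays open. The design gives no group for these wells, and no biological explanation was tested.

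Of all counts, 55.62% lay in the entry for reads assigned to no annotated feature, which depends on the unknown annotation and strand setting.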

How the results depend on the processing

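The scaling without Rn45s and all alternatives of the class comparison were chosen after the data were seen. The germinal center B-like share of 34.8% became 22.0% at resolution 1.0 and also without cell cycle genes, and 30.8% with at least 1000 genes and 100000 counts. The unnamed share of 27.6% became 40.3% at resolution 1.0 and also without cell cycle genes, 22.0% with wells thinned to 1 depth and 22.6% without Rn45s. Leaving out each plate in turn, the plasmablast-like share of 37.7% ranged from 33.3% to 42.1%. The receptor and signalling list's median of -1.44 became -0.86 with median-ratio scaling and -0.82 without a filter on low genes. The STAT6-responsive list's -2.51 became -1.64 with a pseudocount of 10, -1.94 with median-ratio scaling and the filter on low genes applied anew (-1.96 over the same 18 genes), and -1.92 without the filter. The secretory list's 2.97 became 2.78 with a pseudocount of 10 and 3.57 with median-ratio scaling. Apart from the smaller or larger offset built into another pseudocount or scaling, the cause was not tested. The median of the memory B markers, -1.79, was reversed to 0.38 with a filter of 20 CPM, which leaves fewer genes. The 18 list medians of 1 or more in size kept their direction in 359 of 360 alternatives, and the 111 named genes of that size in 1998 of 1998. Most named genes were picked for large ratios in these same cells, and some had named the classes. Most alternatives also reuse the same classes. Changes of direction were therefore unlikely from the outset, and these counts are no independent support. Thinning to 247857 counts left 75 of 751 wells out, and low genes in shallow wells are where depth limits the shares most. The settings meant for the arm comparison, for the immunoglobulin constant genes and for the mitochondrial limit were not run. No paired analysis was possible because no column could be placed in an arm. The classes were instead compared within each of 8 plates, without a test since plates are not replicates. The median over plates was -1.25 for the receptor list, -2.32 for the STAT6-responsive list and 3.01 for the secretory list. Relative to the median of all genes on each plate, these were -0.62, -1.73 and 3.63. The receptor list lay above the median of all genes on 1 of 8 plates.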

Other observations

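The carry-over tests of Igj and Slpi were chosen after their values were seen, whereas the tests of depth and Rn45s on the plate shares were set before their results. A small cluster of 16 cells stayed unnamed in the planned clustering, with 8 of 10 naive or follicular and 7 of 10 memory B markers raised. The clustering without list genes called 17 cells, all unnamed before, naive or follicular B-like, and so did 1000 variable genes, thinned wells and totals without Rn45s. Sell, which encodes the homing receptor L-selectin, and Klf2, a quiescence factor gene, were at 10 CPM or more in 16 of 16 cells, against 1.09% of the other cells for Sell and 37.8% for Klf2. The memory-associated genes Ccr6 and Hhex were each found in 11 cells, Pdcd1lg2 in 9 and Cd38 in 6. Fcer2a was found in 14 and Il4ra in 10 of them. Bcl6, S1pr2, Mef2b and Eaf2 were found in 0 of 16 cells, whereas Eaf2 was in 84.9% of the other cells. Aicda was nonetheless in 9 and Lmo2 in 15 cells, and Itgam, a myeloid integrin gene, in 6. Each plate held 1 to 3 of these cells. These genes were named after their values were seen. Of the other unnamed clusters, 1 held 165 cells with a median of 1880 genes, Bcl6 in 43.0%, Aicda in 57.0% and Sdc1 in 7.27% of cells. The last held 26 cells with a median of 1655 genes, Xbp1 in all 26 and Sdc1 in 42.3%. In the clustering without list genes, unnamed clusters of 49, 39 and 108 cells had medians of 72.1, 32.6 and 18.0% Rn45s. Their median gene numbers were 1634, 1316 and 2087, against 3008 in all kept wells. Wells of low RNA quality may therefore be among the unnamed cells, which was not tested.

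Of 17 measured immediate early and dissociation stress genes, 8 were at least 2-fold higher in plasmablast-like cells, 3 were 2-fold lower and 6 moved less (11 higher and 1 lower relative to the median of all genes). The list's median log2 ratio was 0.99, above 99.47% of random lists and above 0 on 8 of 8 plates. Jun and Ier2 both had a log2 ratio of 4.76, Fos 2.91 and Egr1 2.87. Pro-survival genes had a median of 0.72 (0.39 without 1 naming marker, and 0.34 as the median over plates) and were above 0 on 6 of 8 plates, with 4 genes at least 2-fold higher and 5 lower (8 and 5 relative to the median of all genes), and pro-death genes one of -0.87. Homing receptors had a median of 0.38, with Itga4 at 2.45 and Cd44 at 1.33 but S1pr2, a naming marker, at -4.78 and Cxcr5 at -7.11, and of 17 genes 4 were at least 2-fold higher and 6 lower. Relative to the median of all genes 9 were higher and 4 lower, and with median-ratio scaling 6 and 4. Ribosomal protein genes (-0.85) and housekeeping genes (-0.84) lay near the median of all genes. Medians of interferon response (-0.20), MYC and mTORC1 growth (-0.49), glycolysis (-0.52) and oxidative phosphorylation genes (-0.12) changed sign with median-ratio scaling. Markers of naive or follicular B cells had a median of -2.47, with 8 of 9 genes 2-fold lower, and 5 lower and 1 higher relative to the median of all genes. Marginal zone markers had one of -3.06, with 6 of 9 genes lower and 3 higher and plate medians from -4.95 to 1.21. Memory markers had one of -1.79, with 5 of 8 genes lower and 1 higher, were above 0 on 2 of 8 plates and reversed to 0.38 with a filter of 20 CPM. Their median over plates was -0.52, and they lay above the median of all genes on 4 of 8 plates. Of the sex-linked list, Xist was found in 74.4% of the kept cells. Fewer than 3 genes were measured in it and in the T cell, basophil or mast cell, myeloid, neutrophil, dendritic cell, NK cell and erythroid lists, so no median was taken.

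The plasmablast-like share differed between plates. On plates 1 to 8 in turn it was 15.8, 16.1, 7.37, 13.7, 64.9, 69.2, 61.1 and 54.8%, and the germinal center B-like share 43.2, 44.1, 54.7, 50.5, 26.6, 15.4, 26.3 and 16.1%. The gap of 61.9 points in the plasmablast-like share was 62.32 points with wells thinned to 1 depth and 60.76 points without Rn45s, which argues against depth and ribosomal RNA as its whole cause. Arm, animal and sorting day may each account for it and cannot be told apart, because 0 column names match a label. No biological explanation was tested.

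Igj, which encodes the joining chain of secreted antibody, was found in all 751 kept cells and Slpi, a protease inhibitor gene, in 97.6%, although both are markers of plasma cells, and carry-over alone would hold both to about the ratio of Sdc1, which had 105 reads in germinal center B-like against 119251 in plasmablast-like wells. The ratio of Igj was 71.08 times and that of Slpi 18.78 times that of Sdc1, with plate ranges of 28.0 to 249 and 10.5 to 40.9. Other reference genes rest on few reads and reached 12.24 (Bhlha15) and 10.34 times (Cd28) on single plates, but against the highest of Sdc1, Bhlha15, Creb3l2 and Cd28 on the same plate Igj stood at 7.21 to 45.0 times and Slpi at 2.98 to 14.8 times. A further test, kept after its outcome was seen, used the 5 wells that failed the filter. These wells held Igj at 20285 to 38011 CPM and Slpi at 18487 to 49141 CPM, with 759 reads of Igj, 893 of Slpi and 3 of Sdc1 in all, so a well can hold both without the ratio of plasmablast-like wells. For each Sdc1 read, germinal center B-like wells held 2362 Igj reads, above the upper limit of 1227 in failed wells. The same germinal center B-like wells held 453 Slpi reads for each Sdc1 read, below the limit of 1443. Both limits cover only the counting error of 3 Sdc1 reads. In addition, 1 failed well held 584 of the 759 Igj and 755 of the 893 Slpi reads. The limits leave out the spread between wells and cannot decide, so carry-over stays open as a source of both genes. Expression in germinal center B-like cells may remain as a source of both, and no biological explanation was tested.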
